A study of Homo sapiens with 6 samples.

How the data were processed

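RNA abundance was measured in KYSE150 cells, an established human line of oesophageal squamous cell carcinoma, on 6 one-colour Agilent expression arrays. Per the labels' protocols, the cells were transfected with small interfering RNA using HiPerfect, total RNA was extracted with a mirVana kit, and Cy3-labelled cRNA was hybridised. The labels put 3 arrays in the control group, si-NC, and 3 in the group si-circMAN1A2, named for a circular RNA (circRNA, a ring of RNA closed by a back-splice junction) that takes its name from the gene MAN1A2. The design text and the treatment protocol spell the siRNA group differently, without the circ prefix or with part of the name missing, so the sample labels were followed. The 6 arrays lay on 1 slide scanned 1 time. All 3 si-NC arrays and si-circMAN1A2 replicate 1 lay in slide row 2, and si-circMAN1A2 replicates 2 and 3 lay in slide row 1. Nothing in the labels says that the arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

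The deposited intensity of each spot was produced with Feature Extraction 10.7.1.1, which subtracted the background and detrended the signal across the array, per the file headers. No scaling between arrays was applied to these intensities, per the file headers. The authors also deposited a table of the whole series with the same processed intensities, which lay within 1% of the scanner values for 99.96% to 99.98% of the probes of each array. It also holds log2 values normalized by the authors, whose 6 columns hold identical sorted values with a median of 2.89, as quantile normalization gives; the method is not given in the sources used here. These log2 values were used as an alternative only. Probe coordinates are on the human build hg19 (GRCh37), per the file headers, and the exon and untranslated region annotation of that build was not used here.

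Each array held 62976 spots, 60901 of them for genes rather than controls. Between 43.1% and 45.6% of these spots were well above background on an array, 0 were saturated, and 49 to 102 were left out as outliers. Spots of 1 probe were averaged, which gave 58201 probes, of which 13 lacked a value on an array and 58188 were used. Of these probes, 22504 (38.7%) were well above background on all 6 arrays. Background therefore limits what can be read of dim probes, and the number of arrays limits the precision. The slope of the spike-in controls lay between 0.922 and 0.941 on the 6 arrays. Gene names are those of the array design. Through a RefSeq table of assembly GRCh38.p14, used for names and for which genes contain which others, 31104 probes were matched to a current symbol by accession, 3366 by symbol and 496 by an older symbol, and 23227 had no match.

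The log2 processed intensity of each array was set relative to its 75th percentile, taken over the probes well above background on all arrays because fewer than 50% of the probes were. A constant common to all arrays was added back, so levels are on a log2 scale and are compared within a probe only. A probe was kept if it was well above background on all arrays of at least 1 group, which left 24011 probes of 18601 genes. Each gene took its probe with the highest mean over the 6 arrays. Among 4230 genes with more than 1 kept probe, 2170 were called, and for 1648 of these all kept probes had the same sign. Near-identical copies of a gene can share a probe's signal, among them KRTAP2-3 and KRTAP2-4, KRT33A, KRT33B and KRT34, the SPRR2 genes, CCL3 and CCL3L3, IFNL2 and IFNL3, SERPINB3 and SERPINB4, and copies of small nucleolar RNAs, so their values are uncertain.

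Groups were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with no covariate, 2-sided tests and Benjamini-Hochberg adjustment over all genes kept, and genes were called at an adjusted p under 0.05. Standard errors (SE) of log2 differences come from this fit. A gene not well above background on every array of 1 group has only a bound there. Its change is given as at least N-fold, the mean of the brighter group against the mean over the dimmer group's arrays of the lowest signal among probes well above background, or of the probe's own signal where higher.

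Gene lists were tested with camera at the preset correlation of 0.01, and again with an estimated correlation, and with fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes. Adjustment ran over the 31 lists with at least 5 kept members. The lists cover N-glycan mannosidases and processing, interferon response, NF-kB and cytokine response, G1/S and DNA replication, G2/M and mitosis, p53 targets, apoptosis regulators, epithelial junction and adhesion, mesenchymal and EMT genes, squamous and keratinocyte differentiation, and matrix proteases and invasion. They also cover targets of TGF-beta, YAP/TEAD and WNT/beta-catenin, MAPK immediate early and feedback genes, MYC targets and ribosome biogenesis, the unfolded protein response, the ATF4 integrated stress response, heat shock, hypoxia and glycolysis, sterol biosynthesis, fatty acid synthesis and lipid storage, oxidative phosphorylation, NRF2 targets and replication-dependent histones. The rest are microRNA pathway proteins, circRNA biogenesis and export factors, autophagy and lysosome, and markers of leukocytes, fibroblasts, endothelium, and columnar, liver and neural cells. Endothelial markers were not tested because 2 members were kept. Lists of microRNA families had been planned for a microRNA array only and were not used on this gene expression array.

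Genes were named by a rule. MAN1A2 came first. Then came the 12 genes with the largest increase and the 12 with the largest decrease among called genes well above background on all 6 arrays, not saturated on all arrays of a group, with a proper symbol and no overlap between the groups' arrays. Up to 4 genes of lowest p followed from each list called by camera or fry, up to 5 genes per direction with the largest bound, and up to 4 non-coding RNAs per direction. Members named outside this rule, where 5 or fewer genes of a list went one way or to show what a list held, were chosen after their values were seen. Some genes that the rule selects are not reported here. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined.

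Alternatives were normexp background correction of the raw intensities with offset 50, quantile normalization, scaling to the median, no filter on dim probes, a filter requiring all 6 arrays, the mean of a gene's probes, an intensity trend in eBayes, a t-test per gene, the replicate number as a block, the authors' normalized values, a 2-fold threshold, the other set tests and leaving out each array. Slide or scan batch could not be a block because there was 1 of each. The slide row as a block, the comparison within slide row 2, which sets si-circMAN1A2 replicate 1 against the 3 si-NC arrays, and the 75th percentile over all probes were added after the data were seen. The block and the within-row comparison give the same difference and differ in their error. Within slide row 2 the spread comes from the 3 si-NC arrays and from pooling over genes, and the lone si-circMAN1A2 array is assumed to vary like them.

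The method was tested on simulated arrays of the same 18601 genes, comparing si-circMAN1A2 with si-NC, with 200 genes changed. It recovered 4% of 50 genes changed by 0.25 on the log2 scale, 40% of those changed by 0.5, 72% of those changed by 1 and 96% of those changed by 2. In the data 44.3% of the genes were called, so far fewer genes changed in the simulation, where the Benjamini-Hochberg threshold was therefore stricter. These shares are thus not the recovery in the data. Of 111 genes called in the simulation, 5 (4.5%) were unchanged ones, and the 1 list that had been moved was the 1 list called. Noise was drawn independently for each gene, so the simulation cannot test list calls where genes are correlated. In the data the estimated correlation of the lists called by camera ran from −0.02 for heat shock to 0.47 for NF-kB and cytokine response. Version 1.17.8 of data.table was used, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.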

Results

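Gene expression was profiled in KYSE150 oesophageal squamous carcinoma cells after transfection with a control siRNA, si-NC, or with an siRNA labelled si-circMAN1A2, with 3 arrays in each group. The comparison asks which transcripts differ when the siRNA named for circMAN1A2 is used, in a study that its title places in the regulation between circMAN1A2 and microRNAs. Between 43.1% and 45.6% of the gene spots of an array were well above background. Levels of the 18601 genes kept correlated at 0.997 across genes between arrays of 1 group and at 0.986 to 0.988 between arrays of different groups, where genes are not independent replicates. The first principal component held 73.3% of the variance and separated the groups, and the second held 7.71%.

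MAN1A2, the gene that gives the circRNA its name and encodes a Golgi mannosidase that trims N-glycans, was 1.76-fold lower in si-circMAN1A2. Its log2 level (NM_006699) was 9.05 ± 0.034 (SD, n = 3) in si-NC and 8.23 ± 0.13 (SD, n = 3) in si-circMAN1A2, a log2 difference of −0.82 (SE 0.075; limma, adjusted p = 0.000555). The values of the si-NC arrays were 9.06, 9.01 and 9.08, and those of the si-circMAN1A2 arrays were 8.25, 8.09 and 8.35. This probe lies on chromosome 1 at 118067852 to 118067911 on the plus strand (hg19). A second MAN1A2 probe, at 118039385 to 118039444, was also lower, with levels of 8.14 and 7.78 and a log2 difference of −0.36 (SE 0.079; adjusted p = 0.0126 over probes). With the slide row as a block the difference of the first probe was −0.80 (adjusted p = 0.0121). Within slide row 2 the difference is the same by design, and its test takes the spread from the si-NC arrays (adjusted p = 0.0144). No probe (0) names a circRNA, so the level of circMAN1A2 was not measured, and a probe of the linear transcript does not check an siRNA directed at a back-splice junction.

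In all, 4271 genes were higher and 3967 lower in si-circMAN1A2, which is 44.3% of the genes tested. MAN1A2 ranked 638 from the lowest log2 difference, with 3.42% of genes below it. Most differences were small, since 72.6% of the called genes differed by less than 1.5-fold and their median absolute log2 difference was 0.40, against a median SE of 0.073 over all genes. At least 2-fold changes were found for 305 higher and 339 lower genes. With the slide row as a block 2037 genes were higher and 2295 lower, and within slide row 2, with a single si-circMAN1A2 array, 1768 were higher and 2151 lower. Without the filter on dim probes, which raises the number of genes tested to 43310, 1949 were higher and 2203 lower.

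**Figure D1:**
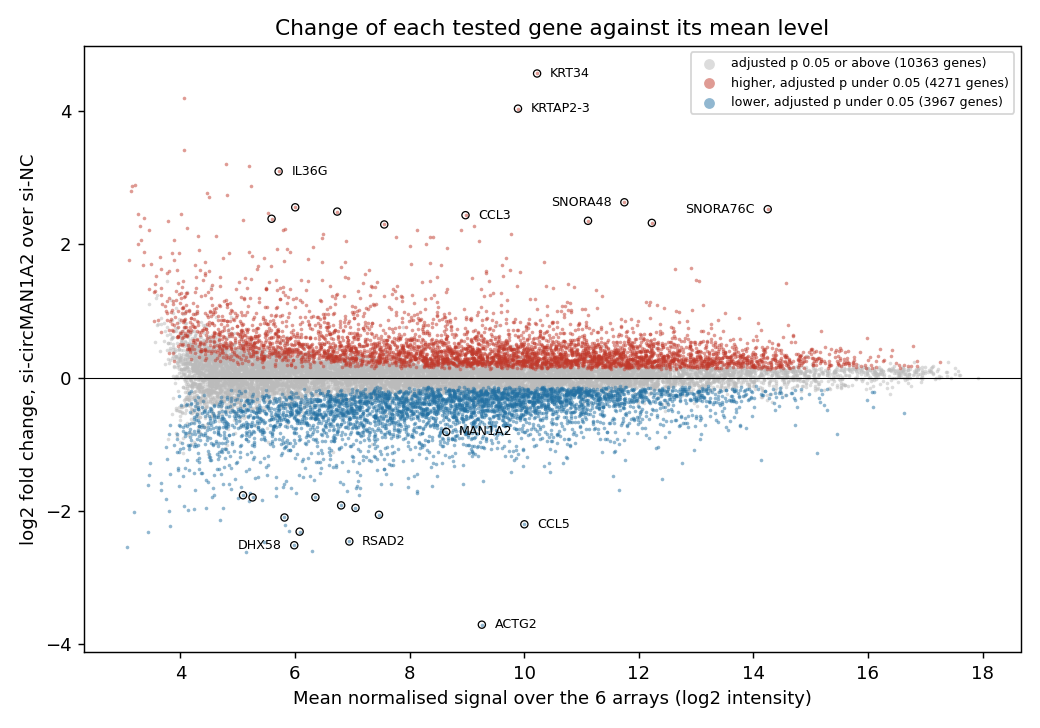
Log2 difference between si-circMAN1A2 and si-NC (vertical axis) against the mean log2 level over the 6 arrays (horizontal axis) for the 18601 genes kept, 1 point per gene, with circles around MAN1A2 and the 12 genes named in each direction. KRT34 lies highest of the circled genes at 4.57, ACTG2 lowest at −3.71, and MAN1A2 at −0.82; uncircled points as far from 0 belong to genes outside the naming rule, such as those with only a bound in 1 group.

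The largest increase under the naming rule was that of KRT34, a hair keratin (NM_021013, chromosome 17, 39534018 to 39534077, minus strand), which rose 23.7-fold, from a log2 level of 7.94 ± 0.18 to 12.51 ± 0.35 (SD, n = 3 each; adjusted p = 0.000109). KRTAP2-3, a hair keratin-associated protein gene, rose 16.5-fold (log2 4.04, SE 0.22), and its probe cannot be separated from its near-identical copy. IL36G, an epidermal cytokine of the interleukin-1 family, rose 8.55-fold (log2 3.10, SE 0.14). SPRR2A, a component of the cornified envelope of keratinocytes, rose 5.63-fold. The chemokine CCL3 rose 5.42-fold and CLDND2 5.23-fold. The other 6 named genes were non-coding. The small nucleolar RNAs (snoRNAs) SNORA48, SNORA76C (now SNORA50C), SNORA10 and SNORA51, of the class that guides pseudouridylation, rose 6.20-fold, 5.77-fold, 5.11-fold and 4.92-fold. The antisense RNA SOX9-AS1 rose 5.89-fold and SNHG19, a snoRNA host transcript, 5.01-fold. Among these 12 genes the highest adjusted p was 0.000276, that of CCL3. With the slide row as a block all 12 kept their call, with log2 differences from 2.10 to 4.32 (highest adjusted p = 0.00481, and 0.0137 within slide row 2).

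The largest decrease was that of ACTG2, the smooth muscle gamma actin (NM_001615, chromosome 2, 74146700 to 74146759, plus strand), which was 13.1-fold lower. Its log2 level was 11.12 in si-NC and 7.40 in si-circMAN1A2, a difference of −3.71 (SE 0.16; adjusted p = 0.000123). Several of the next were antiviral genes. DHX58, an RNA sensor of the RIG-I family, was 5.74-fold lower, RSAD2, which encodes viperin, 5.52-fold, IFI44 3.79-fold and the helicase DDX60 3.48-fold. TNFSF10, the death ligand TRAIL, was 4.98-fold lower, with the highest adjusted p of the 12 (0.00116), and the chemokine CCL5 was 4.61-fold lower. The membrane serine protease TMPRSS4 was 4.30-fold lower, METTL7A (now TMT1A) 4.18-fold, NTNG2 3.89-fold, FAXDC2 3.49-fold and BAHCC1 3.41-fold. The non-coding RNAs LINC01389, USP30-AS1, LINC00707 and NRSN2-AS1 were 3.41-fold, 3.34-fold, 2.95-fold and 2.88-fold lower. With the slide row as a block the 12 genes kept their calls, with log2 differences from −3.33 to −1.70 (highest adjusted p = 0.0124, and 0.0169 within slide row 2).

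Fold sizes of dim genes depended on the background correction. With normexp, which adds an offset, the log2 difference of IL36G was 1.32, of SOX9-AS1 1.26, of SPRR2A 1.64 and of CLDND2 1.12. That of DHX58 was −1.26, of RSAD2 −1.58, of TNFSF10 −1.21, of TMPRSS4 −1.01, of IFI44 −1.22, of FAXDC2 −0.69, of DDX60 −0.91 and of BAHCC1 −0.61. For the non-coding RNAs it was −1.12 for LINC01389, −0.62 for USP30-AS1 and −0.50 for NRSN2-AS1. Each of these genes kept its call. With the mean of its probes, SNORA76C had a log2 difference of 1.54.

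**Figure D2:**
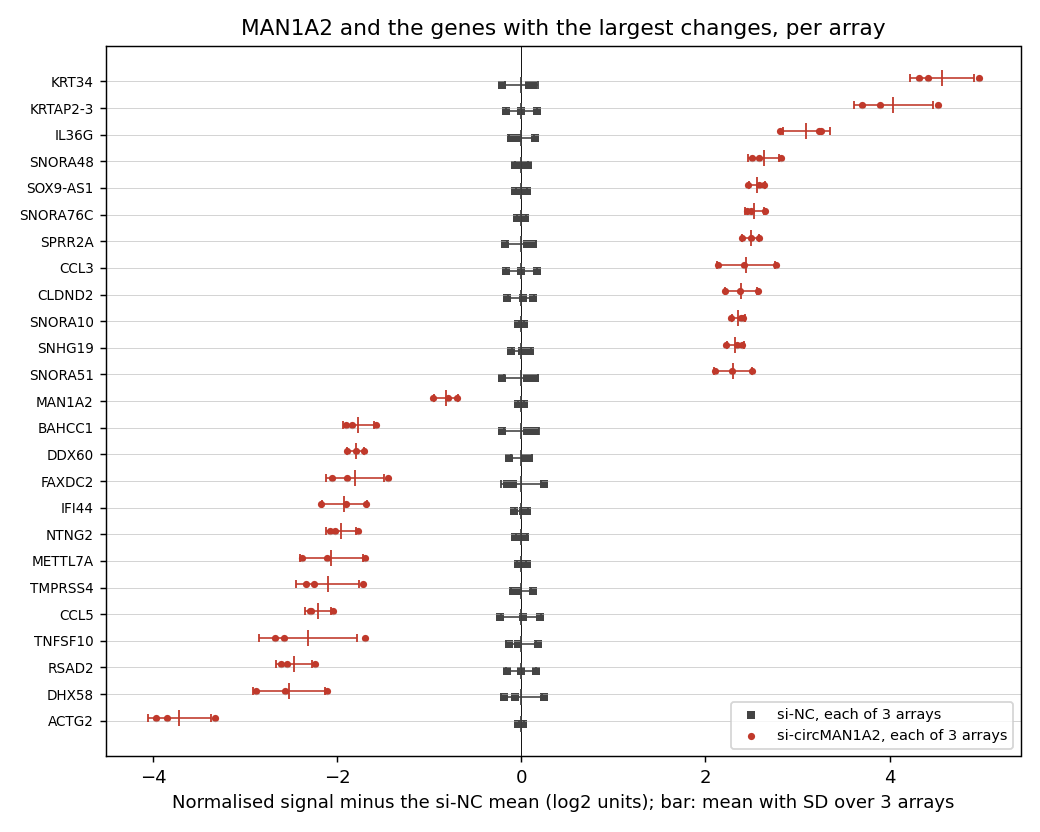
Log2 level minus the gene's si-NC mean, for MAN1A2, the 12 genes with the largest increase and the 12 with the largest decrease. Each point is 1 array (si-NC and si-circMAN1A2, 3 arrays each), with the mean and SD of each group. Before this subtraction the mean level in si-NC and si-circMAN1A2 was 7.94 and 12.51 for KRT34, and 11.12 and 7.40 for ACTG2.

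Some genes were not well above background on any array of 1 group, so only a lower limit of their change is given, which holds for the main background correction alone. In si-circMAN1A2, RFPL4AL1, which has a near-identical copy, was at least 5.59-fold higher (adjusted p = 0.000869), KRBOX1 (now KRABD1) at least 4.72-fold, the hair keratin KRT33B at least 3.79-fold, SNORA38 at least 3.50-fold and CECR6 (now TMEM121B) at least 2.49-fold. The chemokine CCL28 was at least 3.38-fold lower (adjusted p = 0.00246), the collagen gene COL5A3 at least 3.19-fold, the type III interferon IFNL1 at least 2.93-fold, ENTPD5 at least 2.81-fold and C17orf99 at least 2.75-fold. With normexp the log2 differences of RFPL4AL1, KRBOX1, KRT33B, SNORA38 and CECR6 were 1.096, 1.01, 0.71, 0.60 and 0.58. Those of CCL28, COL5A3, IFNL1, ENTPD5 and C17orf99 were −0.49, −0.41, −0.45, −0.38 and −0.43, smaller than the limits given, and all 10 genes kept their calls. Within slide row 2 the call of CCL28 ended (adjusted p = 0.0529). There were 146 such genes dim in si-NC, 114 of them called, and 31 dim in si-circMAN1A2, all 31 called.

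Of the 31 gene lists, camera called 7 at the preset correlation and 0 with an estimated correlation, where 2 lists had an unadjusted p under 0.05. The fry test called 22, and its mixed version, which asks for change in either direction, 29. Neither compares a list with other genes, and 44.3% of all tested genes were called. A fry call, here and below, therefore does not set a list apart from other genes. Of the 24 lists that camera did not call, none was called with the slide row as a block, which moved their medians by at most 0.15 and changed the sign of 1, that of leukocyte markers, to −0.03. Over all alternatives the medians of apoptosis regulators, YAP/TEAD targets, MAPK genes, hypoxia and glycolysis, sterol biosynthesis, oxidative phosphorylation, leukocyte markers, and columnar, liver and neural markers took both signs.

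Interferon response genes fell, with the lowest median of the 31 lists. Of 30 kept members 17 fell, 2 rose and 11 did not pass, and the counts were the same when adjusted over the list alone. RSAD2 fell by 2.46, IFI44 by 1.92, DDX60 by 1.80 and MX1, an antiviral GTPase, by 1.22 on the log2 scale, while IFI35 rose by 0.34 and IFIT5 by 0.32. The median log2 difference was −0.78 (camera, adjusted p = 8.27e-05; adjusted p = 0.608 with an estimated correlation; fry, adjusted p = 0.00236). With the slide row as a block and within slide row 2 the median was −0.60 (adjusted p = 3.94e-05 and 3.45e-05). It was −0.36 after normexp and −0.50 without the filter on dim probes, with the call kept in both, and MX1 was −0.76 after normexp.

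NF-kB and cytokine response genes rose. Of 24 kept members 15 rose and 1, CCL5, fell by 2.21, with the same counts when adjusted over the list alone. The inflammatory cytokine TNF rose 4.01-fold (log2 2.00, SE 0.18), the monocyte chemokine CCL2 2.93-fold (log2 1.55, SE 0.081) and the adhesion molecule ICAM1 1.61-fold. The median was 0.53 (camera, adjusted p = 0.00278; adjusted p = 0.720 with an estimated correlation; fry, adjusted p = 0.0104). It was 0.50 with the slide row as a block and within slide row 2 (adjusted p = 0.00515 and 0.00528).

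Of 29 genes of G1/S and DNA replication 13 fell and 1, MCM5, rose by 0.22, and 15 fell and 1 rose when adjusted over the list alone. The replication genes CDC45, MCM4 and GINS2 fell by 0.40, 0.36 and 0.33. The median was −0.19 (camera, adjusted p = 0.00278; adjusted p = 0.608 with an estimated correlation; fry, adjusted p = 0.00115), and −0.18 with the slide row as a block and within slide row 2 (adjusted p = 0.00565 and 0.00561). Of 33 genes of G2/M and mitosis 12 fell and 1, KIF20A, rose by 0.25, and 10 fell and 1 rose when adjusted over the list alone. The centromere histone CENPA fell by 0.59, CKAP2L by 0.53, the spindle motor KIF11 by 0.36 and the phosphatase gene CDC25C by 0.33, and the call of KIF11 ended within slide row 2 (adjusted p = 0.0520). The median was −0.13 (camera, adjusted p = 0.00362; adjusted p = 0.608 with an estimated correlation; fry, adjusted p = 0.00601), and −0.13 with the slide row as a block and within slide row 2 (adjusted p = 0.0219 and 0.0229). Of 27 replication-dependent histones, also tied to S phase, HIST1H3A (log2 0.17) was higher and HIST2H2AC (−0.26) and HIST1H2AG (−0.24) lower, with 0 and 0 when adjusted over the list alone. The median was −0.07 (limma camera, adjusted p = 0.271; fry, adjusted p = 0.550).

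Epithelial junction and adhesion genes rose. Of 24 kept members 14 rose and 2 fell, with the same counts when adjusted over the list alone. The desmosomal genes DSG3, JUP and DSC2 rose by 0.73, 0.56 and 0.53 on the log2 scale, while the desmosomal cadherin DSC3 fell by 1.03 and the splicing factor ESRP1 by 0.34. After normexp, DSC2 was at 0.31 and DSC3 at −0.68. The median was 0.33 (camera, adjusted p = 0.00361; adjusted p = 0.527 with an estimated correlation; fry, adjusted p = 0.00115), and 0.29 with the slide row as a block and within slide row 2 (adjusted p = 0.00515 and 0.00516).

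Among 22 genes of squamous and keratinocyte differentiation 11 rose and 4 fell, and 11 rose and 5 fell when adjusted over the list alone. SPRR2A rose most, with the cornified envelope gene CNFN at 0.51 and the oesophageal keratin KRT4 at 0.48 (0.24 after normexp). The protease KLK5 fell by 0.72, the basal keratin KRT5 by 0.45, SERPINB3 by 0.88 and SERPINB4, well above background on 2 of the 3 si-circMAN1A2 arrays, by 1.08. The median was 0.19, and camera did not call the list (adjusted p = 0.271), whereas fry did (adjusted p = 0.0272). It was 0.12 with quantile normalization and 0.07 without the filter. Of 14 mesenchymal and EMT genes 8 fell and 5 rose, with the same counts when adjusted over the list alone. The contractile gene TAGLN fell by 0.96 and the matrix genes TNC and FN1 by 0.89 and 0.66, while SPARC was at least 1.65-fold higher (log2 0.27 after normexp). FN1 lost its call after normexp (log2 −0.13, adjusted p = 0.150). The median was −0.31 (camera, adjusted p = 0.262; fry, adjusted p = 0.00115), −0.14 after normexp and −0.20 without the filter. Of 18 genes of matrix proteases and invasion 6 rose and 4 fell, and 7 rose and 4 fell when adjusted over the list alone. The urokinase receptor PLAUR rose by 1.73 and urokinase, PLAU, by 0.79, while the metalloproteinase gene MMP28 fell by 0.90. The median was 0.09 (camera, adjusted p = 0.566; fry, adjusted p = 0.0274).

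Of 17 TGF-beta targets 6 fell and 3 rose, with the same counts when adjusted over the list alone. ID1 fell by 1.48, the inhibitory SMAD6 by 0.86 and PMEPA1 by 0.51, while ID3 rose by 0.52, TGFBI by 0.26 and BAMBI by 0.25. After normexp, SMAD6 was at −0.53. The median was −0.12 (camera, adjusted p = 0.252, and fry, adjusted p = 0.0102). It ranged from −0.17 to −0.05 with 1 array left out. Of 10 WNT/beta-catenin targets 4 fell and 0 rose, and 3 fell and 0 rose when adjusted over the list alone. The transcription factor TCF7 fell by 0.83 and the WNT antagonist DKK1 by 0.69. The log2 differences of CCND1 (−0.26) and RNF43 (−0.20) had adjusted p of 0.0230 and 0.0466, and both calls ended with the slide row as a block (log2 −0.30 and −0.11, adjusted p = 0.0930 and 0.387). That of CCND1 also ended without si-NC replicate 1 or 2 or si-circMAN1A2 replicate 1 or 3 (adjusted p from 0.0663 to 0.0745), and that of RNF43 without any si-NC array or si-circMAN1A2 replicate 2 or 3 (adjusted p from 0.0688 to 0.130). The median was −0.13 (limma camera, adjusted p = 0.413; fry, adjusted p = 0.00578).

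Of 18 YAP/TEAD targets 4 rose and 5 fell, with the same counts when adjusted over the list alone. IGFBP3, which binds insulin-like growth factors, rose by 2.22. The median was −0.04, the mean 0.06 and the camera direction down (camera, adjusted p = 0.712; fry, adjusted p = 0.952). Of 24 MAPK immediate early and feedback genes 4 rose and 4 fell, and 3 rose and 0 fell when adjusted over the list alone. The dual-specificity phosphatase DUSP5 rose by 1.06 and FOSL1 by 0.69, while EGR1 fell by 1.25. The median was −0.00, with camera pointing down (adjusted p = 0.928) and fry up (adjusted p = 0.952).

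Genes of the ATF4 integrated stress response fell. Of 25 kept members 14 fell and 2 rose, with the same counts when adjusted over the list alone. CTH, which makes cysteine, fell by 0.81, the mitochondrial folate enzyme MTHFD2 by 0.42 and the aminotransferase GPT2 by 0.39, while the serine synthesis enzyme PHGDH and SHMT2, which converts serine to glycine, rose by 0.37 and 0.22. The median was −0.25 (camera, adjusted p = 0.00812; adjusted p = 0.688 with an estimated correlation; fry, adjusted p = 0.00812). The median was −0.23 with the slide row as a block and within slide row 2, where the call of the list ended (adjusted p = 0.0908 and 0.0588), as did that of GPT2 within slide row 2 (adjusted p = 0.0506).

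Heat shock genes rose. Of 17 kept members 12 rose and 0 fell, with the same counts when adjusted over the list alone. The co-chaperones DNAJA1, AHSA1 and HSPH1 rose by 0.62, 0.59 and 0.50, and HSP90AA1, the inducible cytosolic HSP90, by 0.39. The median was 0.37 (limma camera, adjusted p = 0.00127; adjusted p = 0.410 with an estimated correlation; fry, adjusted p = 0.000269), and 0.31 with the slide row as a block and within slide row 2 (adjusted p = 0.000787 and 0.000571).

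Among 22 genes of the unfolded protein response 9 rose and 1 fell, with the same counts when adjusted over the list alone. The endoplasmic reticulum genes SDF2L1, DNAJB9 and SEC61B rose by 0.62, 0.37 and 0.29, and the sensor ATF6 fell by 0.67. The call of DNAJB9 ended with the slide row as a block (adjusted p = 0.0779) and, like that of SEC61B, without the filter (adjusted p = 0.0576 and 0.0517). The median was 0.17 (camera, adjusted p = 0.181; fry, adjusted p = 0.00236), and camera called the list without the filter (adjusted p = 0.00290). Of 25 MYC targets and ribosome biogenesis genes 9 rose and 2 fell, with the same counts when adjusted over the list alone. The nucleolar genes NOLC1 and PPAN rose by 0.80 and 0.74 and the spermidine synthase SRM by 0.48, while MYBBP1A fell by 0.34 and WDR12 by 0.29. The median was 0.11 (camera, adjusted p = 0.166; fry, adjusted p = 0.00359), and camera called the list without the filter (adjusted p = 0.00257).

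Of 21 genes of N-glycan processing, the pathway of MAN1A2, 9 fell and 3 rose, with the same counts when adjusted over the list alone. MAN1A2 itself is counted in this list and fell most, by 0.82. The folding sensor UGGT2 fell by 0.58, while the glucosidase genes GANAB and MOGS rose by 0.62 and 0.45 and the branching enzyme gene MGAT4B by 0.30. The median was −0.11 (camera, adjusted p = 0.252; fry, adjusted p = 0.00433), and the median was −0.06 with the slide row as a block and within slide row 2.

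Of 20 microRNA pathway proteins 5 rose and 5 fell, with the same counts when adjusted over the list alone. The Argonaute partner MOV10 rose by 0.46, the exporter XPO5 by 0.30 and the Argonaute gene AGO2 by 0.25, while DICER1 fell by 0.40 and AGO3 by 0.38. The let-7 target HMGA2 was at 0.59 by its brightest probe and at 0.15 by the mean of its 3 probes (adjusted p = 0.0916), which differed in sign. The calls of AGO3 and XPO5 ended within slide row 2 (adjusted p = 0.0538 and 0.0587) and that of XPO5 without the filter (adjusted p = 0.0514). The median was 0.08 (camera, adjusted p = 0.878; fry, adjusted p = 0.00578). Of 24 circRNA biogenesis and export factors 5 rose and 2 fell, and 3 rose and 1 fell when adjusted over the list alone. EIF4A3, of the exon junction complex, rose by 0.29, while HNRNPL fell by 0.23 and QKI, which promotes circularisation, by 0.17. The calls of EIF4A3 and HNRNPL ended without the filter (adjusted p = 0.0710 and 0.107) and within slide row 2 (adjusted p = 0.0714 and 0.102), and with the authors' values EIF4A3 was at 0.19. The median was 0.07 (camera, adjusted p = 0.461; fry, adjusted p = 0.0102).

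Of 24 apoptosis regulators 8 rose and 6 fell, and 9 rose and 6 fell when adjusted over the list alone. The anti-apoptotic BCL2 rose by 0.75 (0.47 after normexp), while the initiator caspase CASP9 fell by 0.46, in addition to TNFSF10. The median was −0.02 and the mean −0.06, whereas both tests pointed up (camera, adjusted p = 0.998; fry, adjusted p = 0.0363). Of 24 p53 targets 7 rose and 4 fell, and 8 rose and 6 fell when adjusted over the list alone. The metabolic regulator C12orf5 (now TIGAR) rose by 0.99 and the translesion polymerase POLH fell by 0.70. The median was 0.08 (camera, adjusted p = 0.878; fry, adjusted p = 0.469).

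Of 29 hypoxia and glycolysis genes 6 rose and 9 fell, with the same counts when adjusted over the list alone and a median of −0.02 (camera, adjusted p = 0.648; fry, adjusted p = 0.550). The carbonic anhydrase CA9 fell by 0.70, and P4HA2, a prolyl hydroxylase of collagen, rose by 0.62. Of 22 sterol biosynthesis genes 3 rose and 5 fell, with the same counts when adjusted over the list alone. Their median was 0.04 and their mean −0.02, with camera pointing down (adjusted p = 0.859; fry, adjusted p = 0.559). Of 19 genes of fatty acid synthesis and lipid storage 6 rose and 4 fell, with the same counts when adjusted over the list alone. The desaturase FADS1 fell by 0.99 and ACSL3, which activates fatty acids, by 0.49, while malic enzyme, ME1, rose by 0.68 (0.44 after normexp). The elongase ELOVL6 was at −0.46 by its brighter probe and at −0.11 by the mean of both (adjusted p = 0.148). The median was −0.09 (camera, adjusted p = 0.859; fry, adjusted p = 0.00572). Of 25 oxidative phosphorylation genes 4 rose and 4 fell, with the same counts when adjusted over the list alone. Their median was 0.01 and their mean −0.01, with camera pointing down (adjusted p = 0.943; fry, adjusted p = 0.952).

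Of 23 NRF2 targets 6 rose and 4 fell, with the same counts when adjusted over the list alone. Haem oxygenase, HMOX1, rose by 1.07 and the ferritin light chain FTL by 0.44, and the call of FTL ended within slide row 2 (adjusted p = 0.0506). AKR1C3 was at 0.72 and lost its call after normexp (log2 0.19, adjusted p = 0.0774) and with the slide row as a block (adjusted p = 0.0605). The median was 0.10 (camera, adjusted p = 0.468; fry, adjusted p = 0.00578). Of 23 autophagy and lysosome genes 8 rose and 6 fell, with the same counts when adjusted over the list alone. The lysosomal hydrolase NEU1 rose by 0.70 and the autophagy receptor SQSTM1 by 0.59, while WIPI1 fell by 0.56. The median was 0.07 (camera, adjusted p = 0.593; fry, adjusted p = 0.00115).

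Of 9 kept leukocyte markers 0 rose and 0 fell, by limma and when adjusted over the list alone, with 0 at an unadjusted p under 0.05 and a median of 0.12 (camera, adjusted p = 0.878; fry, adjusted p = 0.626). Of 7 fibroblast markers 3 rose and 2 fell, and 4 rose and 2 fell when adjusted over the list alone. The collagen genes COL1A1 and COL5A1 rose by 1.45 and 0.66, LUM was at least 1.61-fold higher, and FBLN1 and MMP2 fell by 0.45 and 0.41. The median was 0.35 (camera, adjusted p = 0.578; fry, adjusted p = 0.0699), 0.15 after normexp and 0.09 without the filter. Of 5 columnar, liver and neural markers 2 rose and 0 fell, also when adjusted over the list alone. The cytoskeletal genes MAP2 and TUBB3 rose by 0.65 and 0.33, CDX1 was at 0.18 (adjusted p = 0.143) and APOA1 at 0.21 (adjusted p = 0.277). These last values ranged from 0.12 to 0.25 and from 0.085 to 0.30 with 1 array left out, and were 0.11 and 0.07 after normexp and 0.08 and 0.01 with the slide row as a block. The median was 0.21 (camera, adjusted p = 0.252; fry, adjusted p = 0.00236), and 0.08 with the slide row as a block, and −0.15 without the filter on dim probes, a change of direction. Only 2 endothelial markers were kept and were not tested.

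**Figure D3:**
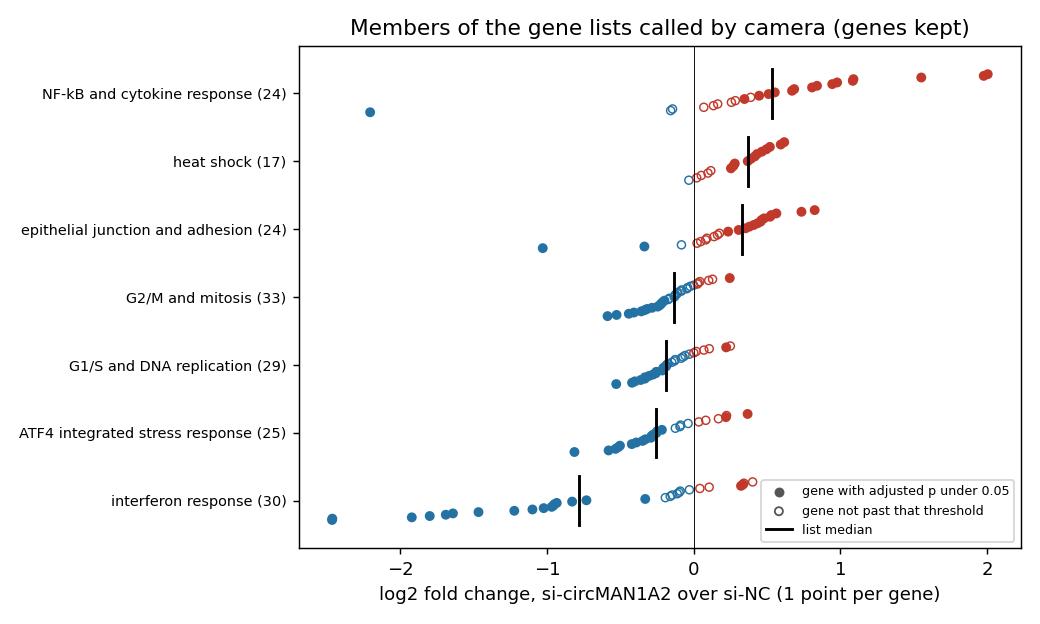
Log2 difference between si-circMAN1A2 and si-NC (axis in log2 units) for the kept members of the 7 lists called by camera at the preset correlation, 1 point per gene, filled where the adjusted p is under 0.05, with a bar at the median of each list. The medians run from −0.78 for interferon response to 0.53 for NF-kB and cytokine response, and members of most lists lie on both sides of 0.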

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

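The slide row alternatives and the 75th percentile over all probes were tests chosen after the results were seen, and the others were planned. Against 4271 genes higher and 3967 lower, the counts stayed within 1.5 times under normexp, quantile normalization, scaling to the median or to the 75th percentile over all probes, the filter on all 6 arrays, the mean of probes, the intensity trend, the t-test per gene and the authors' normalized values, from 3482 (lower, t-test) to 4717 (higher, median scaling). The share of calls that were higher lay between 45.1% and 56.1% over all scalings and slide row settings, against 51.8%. Without the filter on dim probes 1949 genes were higher and 2203 lower among 43310 tested, and 3893 of the original calls were kept. With the slide row as a block 2037 were higher and 2295 lower, with 4194 calls kept in the same direction, and within slide row 2 the numbers were 1768, 2151 and 3764, in designs with fewer arrays behind the contrast. Requiring a 2-fold change gave 305 higher and 339 lower, or 310 and 343 at an unadjusted p under 0.05. Leaving out 1 array at a time gave 3359 to 3711 higher, 3197 to 3568 lower and 7 lists each time. Of 7 lists called, an estimated correlation left 0 and fry called 22, the slide row alternatives gave 6 each and no filter gave 9. The log2 difference of MAN1A2 lay between −0.88 and −0.59, past the threshold in every setting (highest adjusted p = 0.0144). Of the comparisons of named genes with their value under an alternative, 2184 stayed on the same side of the threshold and 47, over 18 of the 119 named genes, lost the call, with 0 reversed; more genes were tested without the filter and fewer arrays stood behind the contrast in the slide row settings, where RNF43 also went from −0.20 to −0.11, and what ended each call was not tested. Normexp moved 38 named genes by more than 1.5 times, all with a mean under 6.93 in the dimmer group, where an added offset shrinks differences, so the background limits fold sizes there more than directions. Of all 8238 genes called in the main fit, 52 were called in the opposite direction with the mean of probes and 4 with normexp. The replicate numbers did not pair the arrays: deviations from the group means correlated at −0.09, −0.06 and 0.01 between arrays of the same number, and not every array correlated best with its own number. With the replicate number as a block, 3591 genes were higher, 3516 lower and 7 lists were called, and the named gene RNF43 lost its call (adjusted p = 0.0821).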

Other observations

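The counts of gene families, the tests of KEGG pathways and of the snoRNA class, and the slide row comparisons, were chosen after the gene results were seen. No family was tested as a set. Among all 18601 genes tested, against which family counts should be read, 4271 rose and 3967 fell. With the slide row as a block these numbers were 2037 and 2295. Of 33 kept keratin genes 16 rose and 4 fell, with a median log2 difference of 0.28, and the hair keratins KRT34, KRT86 and KRT33A lay at 4.57, 0.88 and 0.86 and KRT33B was at least 3.79-fold higher, while KRT15, a keratin of basal cells, fell by 1.24 and KRT23 by 1.01. Of 31 keratin-associated protein genes 9 rose and 0 fell, and of 7 SPRR genes SPRR2A, SPRR2E, SPRR2F and SPRR2C rose, by 2.49, 2.06, 1.14 and 0.97. Among CC and CXC chemokines 9 rose and 4 fell, with CCL3, CXCL8 and CCL2 at 2.44, 1.98 and 1.55 and CCL5 and CXCL11 at −2.21 and −0.79. Of 17 snoRNA host genes of the SNHG series 11 rose, led by SNHG19, SNHG9 and SNHG10 at 2.32, 1.47 and 1.25, and SNHG6 and SNHG7 fell by 0.31 and 0.29. Both of these falls lost their call with the slide row as a block. The sign of each of these families' medians was the same under every scaling and background alternative, with 14 to 16 keratin genes, 9 to 11 keratin-associated protein genes, 4 SPRR genes, 8 to 10 chemokines and 10 or 11 SNHG genes higher. The keratin median ranged from 0.14, after normexp, to 0.30, with 4 to 6 keratin genes lower. The medians of the families named above kept their signs with the slide row as a block too, with 13 keratin genes, 1 keratin-associated protein gene (KRTAP2-3), 4 SPRR genes, 7 chemokines and 9 SNHG genes higher. Of 6 kept genes of the interleukin-1 family 2 rose and 2 fell, with a median of −0.02. That median took both signs under the scaling and background alternatives (−0.07 to 0.009) and was 0.13 with the slide row as a block.

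Of 19 subunits of the vacuolar ATPase, the proton pump that acidifies lysosomes, 13 rose, 1 fell and 5 did not pass, with ATP6V0A1 at 0.89, ATP6V0D1 at 0.75 and ATP6V1E2 at −0.68. Of 37 proteasome subunits of the PSM series 20 rose and 4 fell, and those that fell were PSMB9, PSMD7, PSMB3 and PSMB10, at −0.40, −0.35, −0.30 and −0.28. Under the scaling and background alternatives 12 or 13 ATPase subunits and 13 to 20 PSM subunits were higher, and with the slide row as a block 10 and 8. With that block 2 PSM subunits were lower, against 4 in the main fit. Of 281 KEGG pathways named in the authors' deposited table, camera at the preset correlation called 7 and with an estimated correlation 0 (lowest adjusted p = 0.955, with 8 at an unadjusted p under 0.05). Higher were the synaptic vesicle cycle, which holds the vacuolar ATPase (44 genes, 23 higher and 4 lower, adjusted p = 0.0183), the proteasome (42 genes, 21 and 4, adjusted p = 0.0183) and IL-17 signaling (69 genes, 34 and 9, adjusted p = 0.0458). Lower were beta-alanine metabolism (22 genes, 2 higher and 12 lower, adjusted p = 0.0183), lysine degradation (52 genes, 6 and 24, adjusted p = 0.0458), DNA replication (36 genes, 6 and 19, adjusted p = 0.0460) and the Fanconi anemia pathway of DNA crosslink repair (50 genes, 8 and 28, adjusted p = 0.0183), where BRCA1 fell by 0.78 and FANCI by 0.74. The cell cycle pathway was not called (118 genes, 18 higher and 39 lower, adjusted p = 0.217). The medians of these 7 pathways kept their signs under each scaling and background alternative and with the slide row as a block, but the block left fewer calls. The numbers higher and lower were then 15 and 2 for the synaptic vesicle cycle, 8 and 2 for the proteasome, 15 and 4 for IL-17 signaling, 1 and 7 for beta-alanine metabolism, 3 and 10 for lysine degradation, 2 and 4 for DNA replication and 5 and 13 for the Fanconi anemia pathway.

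Of 190 kept snoRNA genes 107 were higher and 4 lower, a share of 56.3% higher against 22.6% of other genes (Fisher's exact test across genes, which are not independent, odds ratio 4.41, p = 2.34e-23), with a median log2 difference of 0.39 (95% bootstrap interval 0.30 to 0.43) and, with the slide row as a block, 61 higher and a median of 0.40. Without the filter on dim probes 65 of 287 snoRNA genes were higher and 0 lower, with a median of 0.25, and 1949 of all 43310 genes were higher. The median of 104 genes that contain these snoRNAs was 0.085 (interval 0.04 to 0.11), under 50% of the snoRNA median. Over these host genes as a set, this argues against a matching rise in the measured levels of the host transcripts. Even so, 31 host genes were higher and 12 lower. Of 172 snoRNAs with a kept host, 138 had a higher log2 difference than their host. Single hosts did match their snoRNA, as SNHG9 (1.47) matched SNORA78 (1.45). The 17 SNHG genes had a median of 0.28, which is above 50% of the snoRNA median. Host transcription was not measured, so a rise of it stays open. Scaling or background correction as the whole cause is argued against, since the smallest snoRNA median over those alternatives was 0.22, after normexp. That is only a little above the threshold used, 50% of the main median (0.195). The size of the rise thus depended on the background correction. A larger share of every class of small RNA in the si-circMAN1A2 preparations stays open, because 32 other small structured RNAs had a median of 0.25 (interval 0.13 to 0.34), with 10 higher and 1 lower. Most of these were small Cajal body RNAs (SCARNA genes), and the others were uneven. RNU6ATAC and RPPH1 rose by 1.03 and 0.64 and RNU12 fell by 0.25, while RNU2-1 (0.16) and RN7SK (−0.14) were not called. A change in snoRNA processing or turnover with the siRNA, for which no test was run, also stays open. SNORA genes had a median of 0.49 and SNORD genes of 0.28, and the difference between them was not tested.

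Scaling or background correction as the whole cause of the fall of interferon response genes is argued against, since the highest list median over those alternatives was −0.36. The size of the fall depended on the background correction, because the median went from −0.78 in the main fit to −0.36 after normexp. The slide row as the whole cause is also argued against. The slide column was not tested. In slide row 2 si-circMAN1A2 replicate 1 lay in column 1 and the si-NC arrays in columns 2 to 4, so column and group cannot be told apart there. When the list mean of each array was fitted with the slide row, the groups differed by −0.71 (SE 0.11, from the spread between arrays, 95% confidence interval −1.05 to −0.37, 3 residual degrees of freedom). The difference rests on si-circMAN1A2 replicate 1, the only array of its group in the slide row of the si-NC arrays, whose list median lay −0.60 from si-NC (bootstrap interval over genes, which are not independent, −1.03 to −0.16). A lower level of an interferon transcript is a candidate explanation that the data meet. A comparison of levels cannot tell whether such a transcript led to the fall of the list or fell along with it. Of 16 interferon genes on the arrays 13 were well above background on no array, and the 2 well above it on all arrays of a group, IFNL1 (at least 2.93-fold) and IFNL2 (log2 −1.22, adjusted p = 0.00123), were both lower. Whether the si-NC duplex had raised these genes above their level in untransfected cells cannot be told apart from a fall in si-circMAN1A2, because there were 0 arrays of untransfected cells.

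The slide row could add to the number of genes called, since 2 of the 3 si-circMAN1A2 arrays lay in a row without si-NC arrays. As the whole cause it is argued against, because of 7013 genes called without si-circMAN1A2 replicate 1, 92.4% (6483) had that array nearer to si-circMAN1A2 replicates 2 and 3 than to si-NC. This too rests on 1 array, and with the slide row as a block 2037 genes were higher and 2295 lower. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split, 1 of 10, gave 4271 genes higher and 3967 lower by limma. The highest count in the others was 0, with 264 to 443 genes at an unadjusted limma p under 0.05. Each of the others put arrays of both groups on both sides, so the group difference went into the spread. A count near 0 there follows from the design and is no evidence for the real split. Part of the group difference also remained in each of them, which bears on their list calls. For lists, 3 of 10 splits gave as many as the 7 of the real one, the highest of the others being 7. Of the 9 other splits, 6 called the interferon list, 5 the G1/S list, 5 the G2/M list, 4 the NF-kB list, 3 the ATF4 list, 2 the heat shock list and 1 the junction list. Of the 2 other splits with 7 lists, 1 put both arrays of slide row 1 on the same side and 1 put them on opposite sides.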
